A study of Xenopus laevis with 8 samples.

How the data were processed

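The samples were head and tail fragments of Xenopus laevis embryos cut in 2 at stage 18, with 3 single embryos and 1 pool per tissue. Per the labels' protocols, total RNA was purified with TRIzol and spin columns, and biotin-labelled cRNA was made by the manufacturer's procedure with 2 rounds of amplification. The deposited values are intensity values on a linear scale, made with MAS5 per the submitters' processing notes (version not given in the sources used here). MAS5 combines the probes of a probe set into 1 signal per array. On every array the mean signal after leaving out the lowest and highest 2% of values was 1000, so the authors had scaled the arrays to a common level before they were deposited. MAS5 signals of dim probe sets are noisy on a log scale, and the table used here holds signals only, with no detection calls and no scanner values, so the background could not be examined.

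The array has 15611 probe sets, of which 120 controls were left out. Gene names came from the array annotation, with symbols updated through gene identifiers in a RefSeq table of the Xenopus_laevis_v10.1 assembly. Of the other 15491 probe sets, 9304 had 1 symbol, 195 had several and were not named, and 5992 were not listed and stay unnamed here. The update matched 9227 of the 9304 and changed 2 symbols. Xenopus laevis has an L and an S copy of many genes, and probe sets of 1 copy can also bind the other. The copies, and all probe sets of a gene, were treated as 1 gene in the gene lists, each represented by the probe set with the highest mean. The annotation polr2i.S covers many unlike probe sets and was not interpreted. No build was named for the array, so no positions are given.

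Values were raised to at least 1, and log2 values were taken. Probe sets with a mean log2 signal under the 40th percentile, 7.86, were left out, which left 9295 probe sets, 6058 of them with 1 symbol, for 4583 genes. Heads and tails were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 8 arrays without a covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The error given beside a mean is the SD over 4 arrays. Folds are 2 to the power of the difference between mean log2 values. Where the lower tissue's mean lay under the 20th percentile of all values, signal 93.3 (log2 6.54), each array's value was raised to that level first, and the fold is written as at least that size. The same was done for xa-1.L and cfd.L, after their values were seen, because 1 low array moved their folds. The 20th percentile was chosen here and is not a measured background. Pools and single embryos were compared with tissue in the model, and the interaction of tissue and pooling was fitted in the same way. The 22 gene lists were tested with camera at a correlation of 0.01 between genes, for lists with 3 or more tested genes. Camera with an estimated correlation and fry, which asks whether the genes of a set move on balance in 1 direction, were alternatives. Lists share genes: sox2, for example, is in both the placode and the neural list. A list member found only as an older name of another gene was counted under the current name, except ttn, which the table gives as an older name of boc, an unrelated gene.

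Named genes were chosen by a rule fixed before the data were examined. It takes the 12 genes with the largest change in each direction among those past the threshold with 1 symbol, a higher tissue mean above the median of all probe sets and no overlap between heads and tails. It adds up to 4 members of each list that passed, or the 2 brightest where none did, and otx2, six3, ag1, en2, myod1, actc1, tbxt, cdx4, hoxa7 and hoxb9 where measured. No probe set was listed under actc1 alone. For pools and the interaction it takes only genes past the threshold, of which there were none. Genes outside the rule (snap25.L, pax3.L, aplnr.S, both copies of hoxa2 and those under the additional observations) were chosen after their values were seen.

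The alternatives fixed before the data were examined were no filter, a filter at the 60th percentile, quantile normalization, median centring, low values raised to the 20th percentile, a pseudocount of that size, the 6 single-embryo arrays only, array weights, the replicate number as a block, each array left out in turn, other eBayes settings, a 2-fold minimum, 1 probe set per gene, the mean of a gene's probe sets, other set tests, and a model without tissue. Leaving out head replicate 1 and tail replicate 1 together, and the added lists of glycolysis, creatine and DNA replication genes, were chosen after seeing the data.

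The steps were tested on simulated data with the real means and residual spreads of 9295 probe sets. The spreads of the probe sets came from a fit with tissue, pooling and their interaction. Values were drawn independently, so the simulated data hold no deviations shared across genes by an array. Recovery and false calls in the real data can therefore be worse, and the list result does not cover correlated genes. For heads against tails, 38 of 100 changes of 1 log2 unit and 89 of 100 changes of 2 log2 units were recovered, with 4 false calls. For pools against single embryos the numbers were 20 and 68 of 100, with 2 false calls. For the interaction they were 0 and 0 of 100. Both of 2 gene lists moved by 1 log2 unit were recovered over 4583 genes, with 1 false call.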

Results

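Gene expression was measured in the front and the back of Xenopus laevis (African clawed frog) embryos at stage 18, a late neurula in which the neural folds are closing. Each embryo was cut across into a head and a tail fragment, and total RNA of each fragment was hybridised to an Affymetrix array of this species. There were 4 head and 4 tail arrays. In each tissue, replicates 1 to 3 came from 1 embryo each and replicate 4 from a pool of embryos. The labels do not state the clutches, the number of embryos in a pool, or whether a head and a tail of the same number came from the same embryo, so the p-values cover the spread between these samples. The median signal of the 8 arrays ran from 327 to 390 intensity units, and the number of arrays limits the precision. On the first principal component, which held 35.7% of the variance, all 4 heads lay on 1 side and all 4 tails on the other.

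The first comparison asked which genes differ between the fragments. Of 9295 probe sets tested, 429 passed an adjusted p of 0.05 in limma, of which 186 were higher in the head and 243 higher in the tail. The head was marked by genes of the hatching gland, the eye and forebrain, and the cement gland, the mucus-secreting organ at the front of the tadpole. The astacin-type protease gene astl3a.1.L, the hatching enzyme, had a mean log2 signal of 13.51 ± 0.43 in heads and 3.94 ± 0.97 in tails (SD, n = 4 each; limma adjusted p = 4.04e-07). Because the tail signal lay under the 20th percentile of all values, 93.3 units, the difference is given as at least 125-fold. The eye-field homeobox gene six6.L was at least 37.6-fold higher in heads and a second astacin-type gene, astl2e.2.L, at least 18.9-fold. The secreted protein gene crisp1.5.S was 46.2-fold higher in heads, and cyp26c1.S, which encodes a retinoic acid-degrading enzyme, was 24.5-fold higher. The cement gland genes agr2.S and ag1.L were 10.9-fold and 7.99-fold higher, and ag1.L had a mean log2 signal of 15.20 ± 0.27 in heads against 12.20 ± 0.36 in tails (SD, n = 4 each). The forebrain and eye genes otx1.L and pax6.L were 8.67-fold and 7.62-fold higher in heads. The remaining top head genes were ssbp4.S (7.53-fold), xa-1.L, and cfd.L, which encodes complement factor D. The last pair were at least 15.9-fold and 12.4-fold higher, since the tail pool for xa-1.L and tail replicate 2 for cfd.L lay under the 20th percentile; without those arrays the log2 changes were 3.84 and 3.35 against 4.45 and 4.08.

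The tail was marked by the homeobox genes hoxa7.L and hoxc8.S and by genes of unsegmented and segmenting mesoderm. The first, hoxa7.L, had a mean log2 signal of 11.13 ± 0.16 in tails and 4.81 ± 1.34 in heads (SD, n = 4 each; limma adjusted p = 3.44e-05), at least 24.0-fold higher in tails. Its relative hoxc8.S was at least 14.8-fold higher in tails, and a separate probe set annotated xhoxc8 was 10.6-fold higher. The myogenic factor gene myf5.L was 11.5-fold higher in tails, the segmentation gene mespa.S 6.59-fold, and the ventral homeobox gene ventx3.2.S 7.88-fold. The gut endoderm gene darmin.L was 6.05-fold higher in tails. The cholesterol 25-hydroxylase gene ch25h.L was at least 10.3-fold higher and the glutathione peroxidase gene gpx3.S 7.52-fold. The other top tail genes were xmc.L (6.88-fold), pdlim5.L (5.19-fold with low values raised to the 20th percentile) and smtn.S (6.14-fold), the last being the gene of smoothelin, a cytoskeletal protein. Of 4 probe sets of pdlim5 tested, this one alone passed, and the S copy had a log2 change of -0.10.

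**Figure D1:**
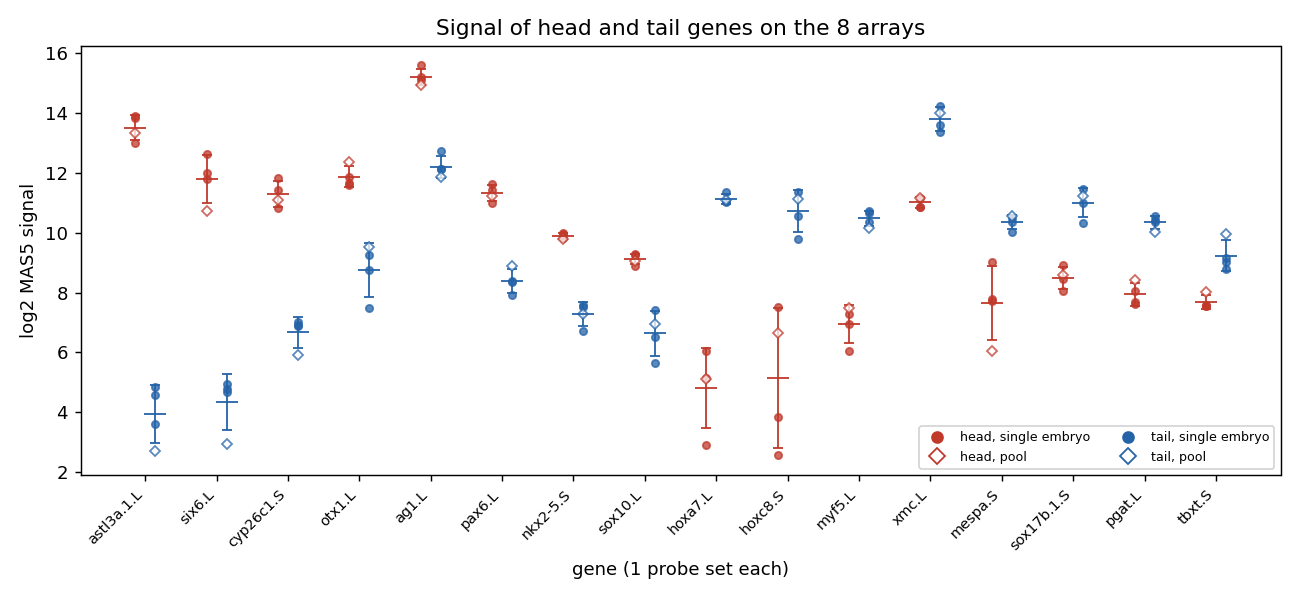
Log2 MAS5 signal (y axis) of 16 named genes (x axis) in heads (red) and tails (blue), with single embryos as filled circles, pools as open diamonds, and horizontal and vertical bars for the mean and SD of 4 arrays. The heads and tails do not overlap for any of the 16 genes, and ag1.L has the highest head mean, 15.20.

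Lists of marker genes fixed before the data were examined were then compared between the fragments with camera, a set test of limma. Of 22 lists, 13 passed an adjusted p of 0.05, 7 higher in the head and 6 higher in the tail. Of 5 cement and hatching gland genes tested, 4 were higher in heads (ag1.L, agr2.S, astl3a.1.L and pitx1.L, the last 4.56-fold) and 1 did not pass (camera adjusted p = 2.17e-07); 4 also passed adjusted over the list alone. Of 11 forebrain and eye-field genes, 6 were higher in heads, among them otx1.L, pax6.L, nkx2-1.L (4.40-fold) and six3.L (3.61-fold), while emx2.L was 4.24-fold higher in tails with low values raised to the 20th percentile (camera adjusted p = 4.90e-07; adjusted over the list alone, 8 higher in heads and 1 in tails). The emx2.L value of head replicate 1, 5.73, lay far below the 8.63 to 8.69 of the other heads; without that array the log2 change was -1.56 against -2.29, and its adjusted p reached 0.121 without tail replicate 3. Of 7 midbrain and hindbrain genes, 2 were higher in heads, irx2.L (2.68-fold) and irx1.L (2.36-fold), and 5 did not pass (camera adjusted p = 0.00212; adjusted over the list alone, 4 higher in heads). Without tail replicate 3 the adjusted p of irx1.L was 0.0798. Of the genes always to be named, otx2.L, en2.L, cdx4.L and hoxb9 had mean signals under the filter; with no filter, otx2.L was at least 4.59-fold higher in heads (adjusted p = 0.00114) and cdx4.L at least 2.28-fold higher in tails (adjusted p = 0.00331), whereas en2.L (mean log2 signal 7.78 in heads and 5.28 in tails, adjusted p = 0.186) and hoxb9 (-0.01, adjusted p = 0.995) did not pass.

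Neural, neural crest and placode lists were also higher in heads. Of 14 neuronal and general neural genes, 4 were higher in heads: the neural progenitor genes sox2.L (4.74-fold) and sox11.S (4.47-fold), the neurofilament-type gene prph.L (3.68-fold) and the proneural gene neurod1.L (2.98-fold). The synaptic gene snap25.L was higher in tails by a log2 change of -1.42 (camera adjusted p = 8.80e-04; adjusted over the list alone, 7 higher in heads and 1 in tails). With the filter at the 60th percentile this list missed the threshold (mean log2 change 0.54 against 0.94, adjusted p = 0.103). Of 17 neural crest genes, 6 were higher in heads, including sox10.L (log2 change 2.48), tfap2b.L (4.38-fold), cdh11.S (3.37-fold) and sox9.S (3.15-fold), and 2 were higher in tails, msx1.L (1.94-fold) and pax3.L (log2 change -0.98). Of 3 pax3.L probe sets tested this one alone passed, the others having changes of 0.51 and 0.01, and the S copy had a change of 1.38. The camera adjusted p of this list was 0.00212 and its adjusted p was 0.0916 with an estimated correlation; adjusted over the list alone, 7 were higher in heads and 2 in tails. With the filter at the 60th percentile its mean change was 0.21 against 0.73 (adjusted p = 0.640). Of 13 placode genes, 4 were higher in heads, sox2.L, sox11.S, neurod1.L and irx1.L, the first 3 of which are also in the neural list (camera adjusted p = 0.0359, and adjusted p = 0.153 with an estimated correlation; adjusted over the list alone, 5 higher in heads and 1 in tails). Leaving out single arrays raised the adjusted p of sox11.S to 0.0942 (without tail replicate 2), that of sox9.S to 0.0894 (without tail replicate 3), that of msx1.L to 0.128 (without tail replicate 3) and that of the placode list to 0.0851 (without tail replicate 1). The placode list also missed the threshold without head replicate 3 (0.0558) and without head replicate 4 (0.0707).

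In the tail, the tailbud and posterior mesoderm list had 22 genes tested, of which 7 were higher in tails and 15 did not pass (camera adjusted p = 2.17e-07; adjusted over the list alone, 13 higher in tails and 1 in heads). They included mespa.S, the signalling gene wnt8a.L (4.52-fold), ripply2.2.S (4.33-fold), the T-box gene tbx6.L (3.96-fold) and tbxt.S, or brachyury (2.94-fold). Of 7 trunk Hox genes (no Cdx gene of this list was tested), 3 were higher in tails, hoxa7.L, hoxc8.S and hoxb7.L (3.03-fold), and 4 did not pass; the camera adjusted p was 1.85e-04 and the adjusted p was 0.0774 with an estimated correlation, and adjusted over the list alone 4 were higher in tails. Germ plasm genes, whose RNAs are inherited by the germ line, were higher in tails for 3 of 4 tested: pgat.L (5.26-fold), ddx25.L (3.36-fold) and ddx4.L (1.95-fold), with a camera adjusted p of 4.72e-07 and all 4 past the threshold adjusted over the list alone. Of 12 endoderm genes, sox17b.1.S (5.68-fold) and darmin.L were higher in tails and gata4.L (2.88-fold) was higher in heads (camera adjusted p = 0.00805, and adjusted p = 0.0774 with an estimated correlation; adjusted over the list alone, 5 higher in tails and 1 in heads). Of 18 epidermal genes, has1.S (2.44-fold) and msx1.L were higher in tails and gata3.S (3.41-fold) was higher in heads (camera adjusted p = 0.01005, and adjusted p = 0.153 with an estimated correlation; adjusted over the list alone, 3 higher in tails and 2 in heads). Without single arrays the adjusted p reached 0.0609 for wnt8a.L (head replicate 3), 0.0995 for ddx4.L (head replicate 2), 0.0601 for has1.S (tail replicate 3), 0.128 for msx1.L (tail replicate 3) and 0.0798 for gata3.S (head replicate 4).

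The difference of the skeletal muscle list, lower in heads, rested on 2 arrays. Of 33 genes tested, myf5.L, nexn.S (3.68-fold) and klhl41.S (2.18-fold) were higher in tails, myl4.S, an embryonic and atrial myosin light chain gene, was 4.41-fold higher in heads, and 29 did not pass; adjusted over the list alone, 5 were higher in tails and 2 in heads. The mean log2 change was -0.25 (camera adjusted p = 0.0114, and adjusted p = 0.549 with an estimated correlation). The list score of head replicate 1, -0.66, lay below the 0.00 to 0.09 of the other heads, and tail replicate 1 had the highest tail score, 0.54. The mean change was -0.07 without head replicate 1 (adjusted p = 0.419), -0.11 without tail replicate 1 (adjusted p = 0.259) and 0.07 without both (adjusted p = 0.731). The muscle determination gene myod1.S had a log2 change of -1.09 (limma adjusted p = 0.225). In tail replicate 1 it was at 8.93, the lowest of the tails (others 9.93 to 10.92), whereas nexn.S, klhl41.S and myl4.S were each highest there. The 3' probe set of the alpha-actin 1 control was also lowest there, 13.04 against 15.02 to 15.50, and that of alpha-actin 3 lay within the range of the other tails. The high list score of tail replicate 1 thus does not hold for every muscle gene. Without head replicate 2 the adjusted p was 0.137 for myl4.S and 0.102 for klhl41.S. The myl4.S value of head replicate 1, 9.97, lay below that of tail replicate 1, 10.49. The log2 change of myl4.S ran from 1.74 to 2.73 when 1 array was left out.

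Cell cycle genes were higher in heads for 6 of 31 tested, among them the kinase gene cdk2.S (3.02-fold), the replication genes cdc45.L (2.70-fold) and mcm4.L (log2 change 1.07), and rrm2.2.L (2.42-fold), which encodes a ribonucleotide reductase subunit (camera adjusted p = 1.46e-05; adjusted over the list alone, 8 higher in heads). The adjusted p was 0.0516 for cdc45.L without head replicate 3 and 0.0928 for mcm4.L without tail replicate 2. No other list passed. Of 13 heart, blood and vessel genes, the cardiac factor genes nkx2-5.S (6.11-fold), gata4.L and nkx2-3.L (2.18-fold) were higher in heads, whereas lmo2.S (4.28-fold), a gene of blood and vessel precursors, and aplnr.S (log2 change -0.94) were higher in tails. This list had a median log2 change of -0.14 and a mean of 0.09 (camera adjusted p = 0.893; adjusted over the list alone, 3 higher in heads and 2 in tails). With the filter at the 60th percentile it passed as higher in tails (mean -0.60, adjusted p = 0.0140), and in the main test the adjusted p of nkx2-3.L was 0.0762 without head replicate 2. Of 8 retinoic acid genes, cyp26c1.S was higher in heads and the receptor gene rarg.S (2.84-fold) was higher in tails (camera adjusted p = 0.0836; adjusted over the list alone, 2 higher in heads and 1 in tails), and the list passed without tail replicate 3 (adjusted p = 0.0480). Of 5 anterior mesendoderm and Wnt antagonist genes, sfrp2.S was 4.07-fold higher in heads (camera adjusted p = 0.978, with a median of -0.07, a mean of 0.21 and a test that leaned to the tail; adjusted over the list alone, 2 higher in each tissue). Of 7 pronephros genes, gata3.S was higher in heads (camera adjusted p = 0.364, median -0.05 and mean 0.33; adjusted over the list alone, 2 higher in heads). Of 12 notochord genes, tbxt.S was higher in tails (camera adjusted p = 0.796, median 0.25 and mean -0.01; adjusted over the list alone, 1 higher in heads and 2 in tails).

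Among the remaining lists, the 3 Hox genes of paralog groups 1 to 4 gave a camera adjusted p of 0.726, with log2 changes of -0.05 for hoxb4.S, -1.05 for hoxa3.S and 0.70 for hoxa2.S (adjusted p = 0.962, 0.155 and 0.348), while the L copy of hoxa2 was higher in heads (1.29, adjusted p = 0.0306); 1 was higher in tails adjusted over the list alone. None of 16 ciliated cell and ionocyte genes passed, over all probe sets or adjusted over the list alone (camera adjusted p = 0.129), and the brightest, tubb4b.L and atp6v1e1.L, had log2 changes of 0.27 and -0.30. The list passed without head replicate 1 (adjusted p = 0.0154). Of 11 housekeeping genes, pgk1, which encodes a glycolytic enzyme, was 2.26-fold higher in tails, also adjusted over the list alone (camera adjusted p = 0.5002). None of 60 ribosomal protein genes passed, over all probe sets or adjusted over the list alone (camera adjusted p = 0.0600), with log2 changes of 0.06 for rpl35a.S and -0.25 for rps13.L. The ribosomal list passed without head replicate 1 (adjusted p = 0.00503), head replicate 4 (0.0277) or tail replicate 1 (4.64e-05).

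**Figure D2:**
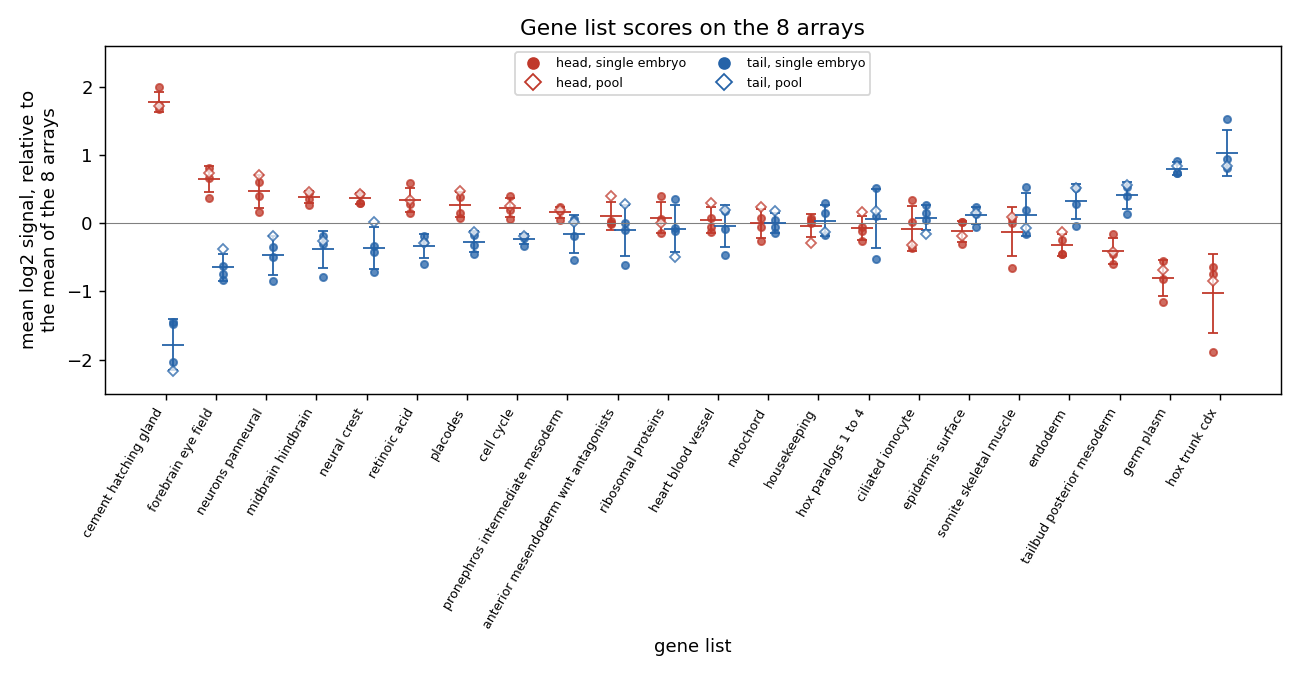
Mean log2 signal of the tested genes of each list relative to the mean of the 8 arrays (y axis) for 22 gene lists (x axis), in heads (red) and tails (blue), with single embryos as filled circles, pools as open diamonds, and bars for the mean and SD of 4 arrays. The cement and hatching gland list lies highest in heads, with 1.99 in head replicate 1, and in the trunk Hox list, whose head values rest partly on signals under the 20th percentile, head replicate 1 stands at -1.89.

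Of the 429 probe sets, 372 differed by 2-fold or more, 416 had no overlap between the heads and the tails, and 1622 had an unadjusted p under 0.05. Over all tested probe sets 1084 had no overlap, against 2.86% of probe sets given by chance. The count was 227 without head replicate 2, 246 without head replicate 3, 277 without head replicate 4, 275 without tail replicate 2, 208 without tail replicate 3 and 211 in the 6 single-embryo arrays, but 479 without head replicate 1, 501 without tail replicate 1, 683 without both, a setting chosen after seeing the data, and 1223 with array weights. In the single-embryo arrays 14 named genes missed the threshold, among them hoxb7.L (adjusted p = 0.0546), rarg.S (0.0559), pgk1 (0.0632) and tbx6.L (0.0814). Of the 13 lists, 7 passed with an estimated correlation: cement and hatching gland, forebrain, midbrain and hindbrain, neural, cell cycle, tailbud, and germ plasm. Among the 34 other ways to part the 8 arrays into 4 and 4, the highest count was 1 probe set and 13 lists. With an estimated correlation it was 0 lists. The real split thus stood alone for the probe sets and the 7 lists, at the smallest p that 35 splits can give, 0.0286. This bears on the counts and not on each probe set or list. The split that also gave 13 lists kept 3 heads on 1 side, so chance is not decided for that count.

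The second comparison asked whether pooled embryos gave the same picture as single embryos. The log2 change of ag1.L was 3.09 in the pools and 2.97 in the mean of the single embryos, and that of nkx2-5.S 2.48 and 2.66. Among the tail genes, the changes were -2.82 in the pools and -2.77 in the single embryos for xmc.L and -2.67 and -3.81 for myf5.L. They lay further apart for mespa.S, at -4.52 and -2.12, and for xhoxc8, at -2.13 and -3.84. The head pool value of mespa.S, 6.04, lay under the 20th percentile of all values, log2 6.54. So did the xhoxc8 value of head replicate 1, 6.31, and the myf5.L value of head replicate 3, 6.06. Without detection calls it is not known whether these signals lie above background, so how far these changes lie apart is uncertain. Of all 9295 tested probe sets, 68.8% changed in the same direction in the pools as in the single embryos. Of 211 probe sets past the threshold in the single embryos, all 211 did. Across these probe sets Pearson's r was 0.963. They were chosen by their change in the single embryos, which favours large changes in both directions and raises r. Across all 9295 tested it was 0.705, with Spearman's rho 0.552. Probe sets are not independent replicates. No probe set passed the test of a different head to tail change in pools and single embryos (limma). At an unadjusted p under 0.05 there were 38, far under the 465 that chance gives, so the unadjusted p-values of this test cannot be relied on. With 1 pool per tissue the test recovered 0 of 100 simulated changes of 2 log2 units.

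**Figure D3:**
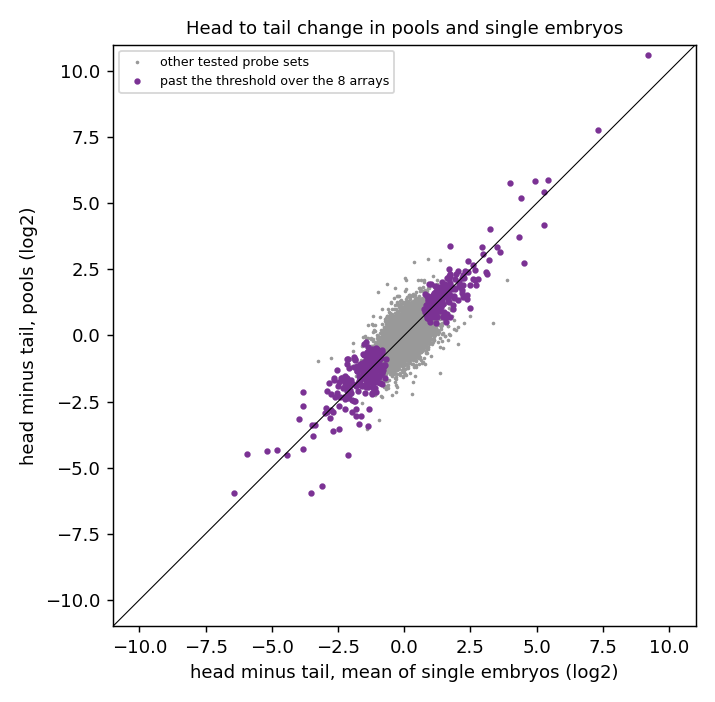
Head minus tail log2 change of each tested probe set in the mean of the single embryos (x axis) and in the pools (y axis), with probe sets past the threshold over the 8 arrays in purple, the others in grey, and a line of equal change. The gene astl3a.1.L, whose tail signals lie under the 20th percentile of all values, lies at the upper right, and r over all 9295 probe sets is 0.705.

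No gene differed between the pools and the single embryos at an adjusted p of 0.05 when tissue was kept in the model (limma, lowest adjusted p 0.103). Chance gives 465 probe sets at an unadjusted p under 0.05. At an unadjusted p under 0.05 there were 1374 probe sets, and 831 of them were higher in the pools; the number was 699 without the head pool and 308 without the tail pool. Named genes that stood apart in a pool included xa-1.L, at a log2 signal of 10.47 in the head pool against 11.14 to 11.18 in single heads. The number past an adjusted p of 0.05 was 2 without head replicate 1 and 2 without tail replicate 3. In those fits 1324 and 1411 probe sets had an unadjusted p under 0.05.

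The spread between single-embryo arrays was of the same order as the median head to tail change. No fragment was measured on a repeat array, so differences between embryos cannot be parted from technical spread. The median change over all tested probe sets also holds both kinds of spread and does not measure the difference between the fragments alone. The median SD over 3 single embryos was 0.31 log2 units in heads and 0.35 in tails, and the median absolute head to tail change in the same embryos was 0.29. In the 2324 brightest probe sets the median SD was 0.27 in heads and 0.30 in tails, and in the 2324 dimmest it was 0.35 and 0.40. Over all 4 arrays, nkx2-5.S had an SD of 0.11 in heads and rpl35a.S one of 0.23, whereas the dim head values of hoxc8.S had an SD of 2.33. Without head replicate 1 the median SD in heads was 0.21, against 0.26 and 0.29 without head replicate 2 or 3. Without tail replicate 1 that in tails was 0.22, against 0.30 and 0.34 without tail replicate 2 or 3. These are SDs over 2 arrays and cannot be set directly against those over 3.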

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

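The tests of the muscle genes, of scaling and control ratios in the pools and of the probe sets that parted the embryos were chosen after the results were seen, as were the arrays numbered 1 left out in a test of the pools; the tests of the other splits of the arrays were not. Each gene and list named was examined for an array far from the other 3 of its tissue. Of 186 groups of 4 arrays, 14 had one, where 9.3 were given by chance, since chance gives about 1 in 20.

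The head and tail split gave 429 probe sets. Of the 35 ways to part the 8 arrays into 4 and 4, 1 gave as many, the real one. The highest of the others gave 1. With 35 splits the smallest p that this exact test can give is 0.0286. It bears on the count and not on single probe sets. For the gene lists at the preset correlation, 2 of the 35 splits gave 13 or more lists. The other one also gave 13 and exchanged head replicate 2 for tail replicate 3. It still set 3 heads against 3 tails and so kept part of the tissue contrast. Splits with 2 heads and 2 tails on each side gave 0 to 4 lists. The count of splits thus cannot decide on chance for the 13 lists. With an estimated correlation the real split gave 7 lists and the highest of the others 0, and 1 of the 35 splits gave as many.

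Head replicate 1 stood apart from the other heads in 7 results. Its muscle list score was -0.66 (others 0.00 to 0.09) and its trunk Hox list score -1.89 (others -0.84 to -0.64). The log2 signals were 5.73 for emx2.L (others 8.63 to 8.69), 5.22 for pdlim5.L (7.21 to 7.57), 9.82 for irx1.L (10.66 to 10.77), 13.77 for rrm2.2.L (13.17 to 13.26) and 11.55 for rarg.S (10.31 to 10.51). In the head pool, tbxt.S was at 8.02 (others 7.54 to 7.57), xa-1.L at 10.47 (11.14 to 11.18) and the anterior mesendoderm list score at 0.41 (-0.01 to 0.03). In the tail pool, xa-1.L was at 4.71 (7.11 to 7.24), cyp26c1.S at 5.91 (6.89 to 7.02) and six6.L at 2.95 (4.67 to 4.96). These tail pool values, all tail values of six6.L, and those of emx2.L and pdlim5.L in head replicate 1 lay under the 20th percentile. Without detection calls it is not known whether such signals lie above background. Tail replicate 1 had myl4.S at 10.49, against 9.23 to 9.35 in the other tails.

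The muscle list's difference rested on head replicate 1 and tail replicate 1. In head replicate 1 the median deviation of the 33 muscle genes from the other heads was -0.68, at percentile 0 of 10000 random lists matched on signal, which argues against scaling of that array. Had head replicate 1 been cut further forward, its tailbud score would be below that of the other heads; it was above them, at -0.15 against -0.60 to -0.42. The trunk Hox score points the other way, at -1.05 against -0.87 to -0.41 with low values raised to the 20th percentile, so the plane of the cut stays open. A difference in age between embryos within stage 18 was not tested and stays open, as does the quality of the RNA.

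No probe set passed between pools and single embryos, and 1374 had an unadjusted p under 0.05. This was the second highest count of 16 pairs of a head and a tail set against the other 6 arrays. Of the other pairs 1 gave more, 1985, and the next gave 1097 and 683. For the pools there were 1413 after quantile normalization, which argues against scaling as the cause of the count. Without head replicate 1 and tail replicate 1, which lay at the opposite end, there were 1534, which argues against those arrays as the cause, although that pair itself gave the 1985, with 15 probe sets past the threshold against 0 for the pools. The ratio of the 3' to the middle probe set of the alpha-actin 1 control was highest in the pools, 7.84 in the head pool (at most 6.51 in single heads) and 9.10 in the tail pool (at most 6.34 in single tails), while of the 3 other controls none was highest in the head pool and 2, alpha-actin 3 and beta-actin, were in the tail pool. RNA quality thus stays open, as do pooling and shared handling, which lie in the same arrays, and no biological explanation was tested.

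Across both tissues, 5 probe sets parted the single embryos into a high and a low set by a gap of 3 log2 units or more. The probe set of LOC100158288 had log2 signals of 15.65, 10.33 and 10.46 in single heads and 11.26, 15.56 and 10.31 in single tails, with 15.28 and 15.41 in the pools. If the level were fixed per embryo and same-numbered fragments came from 1 embryo, a head and a tail of 1 number would lie on 1 side; in 5 of 5 probe sets at least 1 pair did not, and in 3 of 5 no matching of heads to tails would do so. Whether the whole gene differed stays open, because polr2i.S, among the 5, was left out of the comparison for its unlike probe sets, and of the other genes sfxn2.S alone had other probe sets; 0 of these was parted the same way by over 1 log2 unit.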

How the results depend on the processing

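The count of 429 probe sets, head against tail, was 273 with the 60th percentile filter, 239 with 1 probe set per gene, 211 in the single embryos and 1223 with array weights, and 208 to 501 without single arrays; the first 3 settings test fewer probe sets or arrays, and for the others the cause was not tested. Without head replicate 1 and tail replicate 1 together, chosen after seeing the data, it was 683. The 13 gene lists became 8 with the 60th percentile filter, 7 with an estimated correlation, and 12 to 14 without single arrays; 11 of the 13 passed in all 8 fits without 1 array. With the 60th percentile filter the neural, neural crest, placode and muscle lists missed the threshold (adjusted p = 0.103, 0.640, 0.300 and 0.0717), the midbrain and trunk Hox lists had too few genes to test, and the heart list passed. With fry 13 passed, 9 higher in heads and 4 in tails: the muscle (0.430) and epidermal (0.0640) lists were lost and the pronephros (0.0407) and retinoic acid (0.00582) lists gained. Pools against single embryos gave 0 to 2 probe sets without single arrays and 0 under the other settings run, and the interaction gave 0 under all settings run. The correlation between pools and single embryos was 0.420 with no filter, which adds dim probe sets, 0.963 over probe sets past the threshold in single embryos, and 0.622 to 0.718 without single arrays. The median SD between single embryos was 0.39 in heads and 0.43 in tails with no filter, and 0.21 to 0.29 and 0.22 to 0.34 without single arrays.

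The replicate number as a block gave 635 probe sets and 12 lists. The numbers share no known origin: the deviations of same-numbered single embryos correlated at r = 0.0853, 0.0697 and 0.0575, and 4 of 6 single arrays correlated best with their own number. Those deviations were taken from the mean of the 3 single arrays of a tissue. Taken from the mean of all 4 arrays, the pairs numbered 1, 2 and 3 correlated at r = 0.226, 0.0342 and 0.0181. On that basis the pools correlated at r = 0.596. The block moved 3 other calls: the placode list (adjusted p = 0.0619) and myl4.S (0.0598) missed the threshold and hoxa3.S passed it.

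Of 64 named probe sets past the threshold, 50 passed in all 8 fits without 1 array, 14 missed the threshold in the single-embryo arrays, 18 missed it at least once, and none reversed under any setting. The muscle list reversed to 0.0659 without head replicate 1 and tail replicate 1. The other reversals were of results that had not passed. With no filter the notochord list was at 0.0132 and the anterior mesendoderm list at -0.0107. With the 60th percentile filter the heart list was at -0.60 against 0.09 (adjusted p = 0.0140) and the retinoic acid list at -0.34 against 0.68. With array weights the notochord list was at 0.0573 and the heart list at -0.0366, and without both arrays numbered 1 the notochord list was at 0.0275. The gene rpl35a.S was at -0.0121 with median centring and -0.0374 in single embryos. Without single arrays, the ranges were -0.0845 to 0.0785 for the notochord list, -0.0130 to 0.17 for the heart list, -0.15 to 0.0102 for housekeeping genes, -0.33 to 0.0146 for Hox paralog groups 1 to 4, -0.42 to 0.20 for hoxb4.S and -0.0503 to 0.16 for rpl35a.S. The cause was not tested for any of these. The ribosomal protein list, which did not pass, passed with quantile normalization (mean 0.19, adjusted p = 0.00551) and without tail replicate 1 (0.31, adjusted p = 4.64e-05), against 0.02 without tail replicate 4. Without detection calls, changes of dim genes rest on signals that the background cannot be told from.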

Other observations

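The gene sets in this part, and the other splits for the L and S copies, were chosen after the data were examined, while the test on the DNA replication and glycolysis genes that had not passed was fixed before its result was seen. Of 28 tested genes of DNA replication and chromatin assembly, 11 were higher in heads and none higher in tails. They included the histone chaperone genes asf1b.L (log2 change 1.68, adjusted p = 8.27e-04) and nasp.L (1.00, adjusted p = 0.0241), the helicase gene mcm6.2.L (1.35, adjusted p = 0.00351) and the clamp loader gene rfc4.L (1.28, adjusted p = 0.0103). The mean change of the set was 0.77 with all arrays and 0.75 without head replicate 1 and tail replicate 1; 9 of the 28 genes are in the lists fixed beforehand. A hypothesis is that the difference extends to the members that had not passed. Over 12 such genes in no fixed list the mean log2 change was 0.54, in the predicted direction (camera with an estimated correlation, p = 0.0296). These genes belong to a set chosen after the data were examined and were measured on the same arrays. The result is thus not independent support for the hypothesis.

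Of 19 tested glycolysis genes, pgk1 (log2 change -1.18), pgam1.S (-1.15), gpi.S (-1.14) and pfkfb1.S (-1.50) passed and none was higher in heads. As a set the 19 passed as lower in heads, with a mean of -0.36 (camera adjusted p = 8.07e-04, and adjusted p = 0.0141 with an estimated correlation). Without the arrays numbered 1 the mean was -0.32 (camera adjusted p = 0.0329). The 11 members that had not passed and were in no fixed list had a mean of -0.24 and a median of -0.09. Their p was 0.0974 (camera with an estimated correlation), so a difference over the rest of the pathway was not shown. Both genes of creatine synthesis, gamt.S (-1.21, adjusted p = 0.0202) and gatm.L (-1.19, adjusted p = 0.0114), and the creatine kinase gene ckmt1b.S (-1.34, adjusted p = 0.0319) were higher in tails, whereas ckm.L (-0.17, adjusted p = 0.856) and ckb.L (0.63, adjusted p = 0.353) did not pass. As a set the 5 creatine genes did not pass with an estimated correlation (adjusted p = 0.0924) or without the arrays numbered 1 (0.0926).

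Of 626 genes with L and S copies tested, the log2 changes of both copies had the same sign in 68.1%. Under the 34 other splits of the 8 arrays into 4 and 4 the share was 58.0% to 70.4%, and 6 were as high. The share thus does not set the real split apart. Some of the others kept 3 heads on 1 side and so part of the tissue contrast, so they do not measure array deviations alone. Among the 626, 39 had a copy past the threshold, and in 35 of these both copies changed in the same direction. In 17 both copies passed, all 17 in the same direction, among them ag1, mycn, msi1, vim, smtn and nr5a2. Probe sets of 1 copy can also bind the other, so the values of the copies are not independent and part of the agreement can come from this. Across the 626 pairs r was 0.601, against a median of 0.458 and a highest value of 0.616 in the other splits, of which 1 was as high. The difference between copies passed an adjusted p of 0.05 (limma on the L minus S value of each array) for 9 genes, with 80 at an unadjusted p under 0.05. They included krt19 (log2 change 0.33 in L and 2.39 in S), anxa1.1 (1.87 and -0.59), pdlim5 (-2.38 with low values raised to the 20th percentile, and -0.10), six6 (at least 5.23 and 1.71, the L copy's tail signals lying under the 20th percentile of all values) and pax3 (-0.98 and 1.38). Of 3 pax3.L probe sets tested, the other 2 had changes of 0.51 and 0.01, so the pax3 difference rests on 1 probe set.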
